A study of Mus musculus with 43 samples.

How the data were processed

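E14 mouse embryonic stem cells were studied by ChIP-seq for MTF2, SUZ12 and H3K27me3 in control cells, MTF2 knockout cells and knockout cells carrying wild-type or K339A MTF2, and by RNA-seq in control and knockout cells. The 43 samples were grouped from their labels into 36 ChIP-seq samples, 1 input sample and 6 RNA-seq libraries, 3 per group. RNA was total RNA from which polyadenylated RNA was taken with oligo-dT beads, per the labels' protocols. The ChIP-seq samples were not analysed here.

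The analysis started from 1 gene table. The submitters' processing notes name Bowtie 1.0, deepTools, TopHat2 2.1.0 and Cuffdiff 2.2.1.3, and the builds mm9 and mm10, with no role given for any. The FPKM values (fragments scaled to transcript length and to library size) were made by the authors, 1 pooled value per gene and group, per the file headers, and the scaling between libraries is not given in the sources used here. The log2 fold change deposited by the authors is knockout over control with no pseudocount, and differed from the log2 of the deposited FPKM values by at most 1.29e-05 in tested genes. The p-value and q-value were made by the authors, and the deposited q equals a Benjamini-Hochberg (BH) adjustment of the deposited p over the 11362 genes with status OK to within 5.2e-07. The deposited test statistic is a score of the log ratio over its estimated error by the authors' tool. The deposited p were smaller than a normal p from that score: the normal z of p was 1.73 times the score at the median over 7294 genes. The smallest deposited p was 5e-05, which gives the q of 0.0012 shared by 472 called genes.

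The table held 22462 genes, of which 11098 had status NOTEST and 2 FAIL and were left out of tests. Coordinates were taken from the table, with starts moved from 0-based to 1-based. Of 21120 genes matched by symbol to RefSeq on GRCm38.p6, the reference of mm10, 99.99% lay on the same chromosome and 89.0% within 2 kb of their locus entry, so coordinates are given as mm10. Locus entries can be merged spans, and 3725 genes share an entry. Of the gene IDs, 18304 were in the ID table at hand, and symbols came from the table itself.

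Library depth is unknown, since the FPKM were pooled and no counts were used. Summed FPKM was 559237 in control and 504845 in knockout cells. The ratio used throughout is log2((knockout FPKM + 0.5)/(control FPKM + 0.5)), which understates changes of low genes. Calls are the authors': status OK and q at or under 0.05. As the table holds no values per library, no test across replicates, SD or leave-one-out could be made here. The q values are the authors' adjusted p and do not give the spread between libraries.

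Before the data were examined, 28 gene lists with 942 entries were fixed. Each was tested against all other tested genes with a two-sided Fisher's exact test in both directions, with BH adjustment over the 56 tests. Genes are not independent replicates, so these p describe the authors' calls. The median log2 ratio of each list was set among 10000 random lists matched on mean FPKM in 20 bins. Chromosome medians used genes with FPKM of 1 or more in either group and 10000 random gene sets, and neighbouring calls were compared with 10000 shuffles. After the data were seen, running medians of 50 genes in steps of 5 were added, with a threshold of 0.51 from the 95th percentile of the largest absolute median in 1000 shuffles. Windows above it were merged, and segment ends were trimmed until the median of the outermost 5 genes passed it. To measure segments on genes not used to find them, the scan was also run on every second expressed gene with windows of 25 genes and a threshold of 0.71. Intervals of medians are 95% bootstrap intervals from 2000 draws of genes.

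Named genes followed a rule fixed before the data were examined: Mtf2 and the PRC2 list, the 10 higher and 10 lower calls with the largest ratio at FPKM of 1 or more (leaving out Gm, LOC, Rik, Mir and Snor symbols), and up to 2 higher and 2 lower calls per list. Other genes were named after their values were seen: Eif2s3y, Sox7, Pdgfra, Gata6, Lamb1, Sparc, Sox17, Cited1, Foxa2, Pou5f1, Nanog, Sox2, Esrrb, Epcam and Atf4, and the genes of the closing section that are in none of these. Some genes that the rule takes are not reported here. Alternatives planned beforehand were a q of 0.01, a 2-fold minimum, an FPKM filter, recomputed BH, a normal p from the test statistic, median centring, pseudocounts of 0.1 and 1, a background of expressed genes, a Mantel-Haenszel test over 10 expression bins, 1 list member per run within 200 kb, an FPKM of 5 and a 10% trimmed mean for chromosomes, and neighbours within 50 kb.

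The list test and the running medians were also run on simulated data, made by shuffling the calls and ratios over the genes. For the running medians, the simulation came after the data were seen. Of 160 planted lists of 25 genes, 96.2% were recovered among 11362 genes, and 0.25% of unchanged lists were called. Each planted member was set to a higher call with a chance of 40%, on top of the shuffled calls. Lists with a smaller share of calls, such as 9 of 37 in the imprinted list, were not planted. Shuffling single genes also removed the clustering of neighbouring calls, so these rates may not hold for the real lists. All 20 planted rises of 0.9 over 120 genes were recovered among 11986 genes with 0 segments elsewhere. Of 20 simulations without a rise, 3 gave a segment. Only rises of about the size of the raised segments were planted, so recovery of a lowered segment with a median of -0.56 was not tested. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.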

Results

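MTF2, also called PCL2, is 1 of the Polycomb-like subunits of Polycomb repressive complex 2 (PRC2), the enzyme complex that methylates lysine 27 of histone H3. The series compared E14 cells, a male mouse embryonic stem cell line grown here with LIF on gelatin, with a knockout of MTF2 in the same line. It also held cells in which wild-type MTF2 or the K339A mutant was put back. The 43 samples comprised 36 ChIP-seq samples, 1 input sample and 6 RNA-seq libraries, 3 from control and 3 from knockout cells. The series design calls the replicates biological. The gene expression results rest on the 6 RNA-seq libraries: the authors' deposited table gives 1 pooled FPKM value per gene and group, and every FPKM value printed here is that pooled value. No SD or n per value can therefore be given, and the depth per library is unknown. The ChIP-seq samples were not analysed here.

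The first comparison asked whether the targeted gene was lower in the cells labelled knockout. In the authors' deposited table, Mtf2 (chromosome 5, 108065742 to 108132620, mm10) stood at 74.3 FPKM in control and 44.7 FPKM in knockout cells. Its log2 ratio was -0.73, with a Cuffdiff q of 0.0496 in the authors' deposited table. Transcripts were thus lower but still present at 60.2% of the control level. The table does not say which exons the remaining transcripts held, so it is a weak check of the labels. Mtf2 is 1 of 2 genes sharing its locus entry. The call was lost at a q of 0.01 and with a p computed from the deposited test statistic (q = 0.755).

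The PRC2 list held 13 tested genes. 3 were called lower, 0 higher and 10 were not called, with 3 lower and 0 higher adjusted over the list alone. Besides Mtf2, the called genes were Phf19, another Polycomb-like gene, at 457 FPKM in control and 149 FPKM in knockout cells (log2 ratio -1.61, q = 0.0107), and Aebp2, at 81.3 and 33.6 FPKM (log2 ratio -1.26, q = 0.0012), both per the authors' deposited table. The catalytic subunit Ezh2 (78.6 and 65.7 FPKM), Suz12 (35.1 and 25.5 FPKM), Eed (868 and 777 FPKM), Jarid2 (108 and 98.1 FPKM) and Epop (353 and 248 FPKM) were not called. The same held for Ezh1 (7.44 and 9.05 FPKM), Rbbp4 (33.2 and 37.5 FPKM), Rbbp7 (75.9 and 75.6 FPKM), Phf1 (18.1 and 18.9 FPKM) and Lcor (6.67 and 5.50 FPKM).

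The second comparison asked which genes differed between knockout and control cells. Genes of the primitive endoderm list were among the largest gains. Col4a2, a basement membrane collagen chain, went from 4.86 to 159 FPKM, Col4a1 from 6.49 to 185 FPKM, the transcription factor Gata4 from 2.17 to 71.7 FPKM and the adaptor protein gene Dab2 from 0.526 to 30.3 FPKM. The other genes with the largest called gains were Aqp8, a water channel listed at 0 in control and 17.8 FPKM in knockout cells, Hkdc1 (0.277 to 27.7 FPKM), the cathepsin gene Ctsh (0.757 to 41.9 FPKM), the keratin gene Krt19 (0.554 to 35.0 FPKM), Clu (3.40 to 126 FPKM) and Ankrd1, listed at 0 and 12.8 FPKM. The largest called losses were Plagl1, Stra8, Fam183b, Rhox13 and Pla2g2e, all listed at 0 in knockout cells and at 18.3, 12.1, 7.62, 6.68 and 5.40 FPKM in control cells. They also included Nnat (77.6 to 4.50 FPKM), Arl14epl (14 to 0.444 FPKM), Rpl10l (99.2 to 6.54 FPKM), Stmn2 (126 to 11.7 FPKM) and Tuba3a (59.2 to 5.86 FPKM). All of these values come from the authors' deposited table. Among the gains, Col4a1 and Col4a2, which share a locus entry, lie in a part of chromosome 8 where most expressed genes were higher. Gata4 and Clu lie in such a part of chromosome 14.

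**Figure D1:**
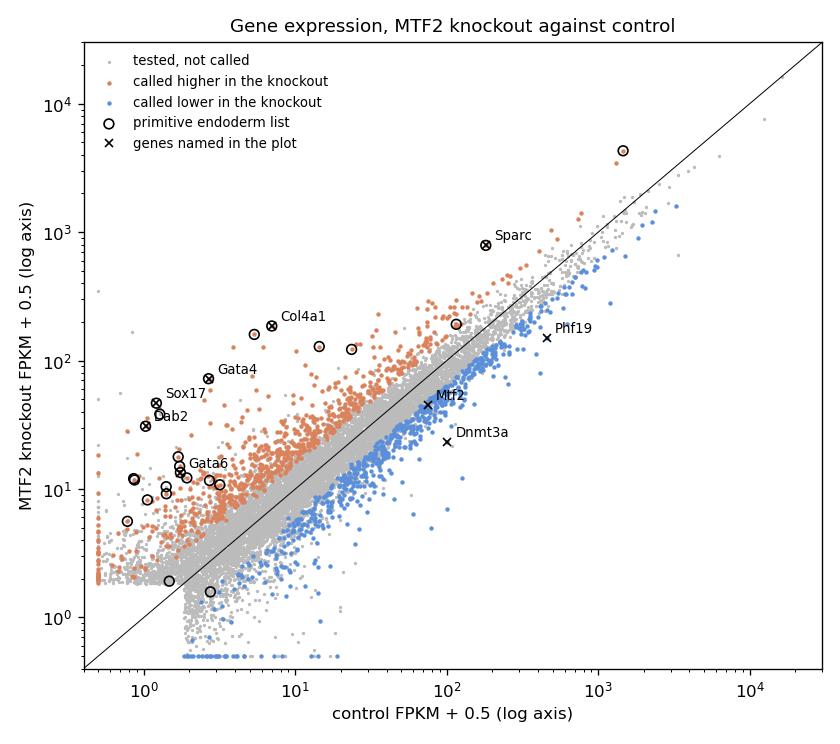
Pooled FPKM + 0.5 in control (x axis, log scale) against MTF2 knockout (y axis, log scale) for the 11362 tested genes, with called genes coloured, the tested primitive endoderm list circled and 9 genes marked with a cross; the line marks equal values. Of 25 tested members of the primitive endoderm list, 24 lie above the line.

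In total, 784 genes were called higher and 685 lower at a Cuffdiff q of 0.05 among 11362 tested genes in the authors' deposited table, which is 12.9% of those tested. The median log2 ratio of the called genes was 1.23 for the higher and -0.95 for the lower ones, and the median over all tested genes was -0.0035. Of the calls, 531 higher and 318 lower genes changed at least 2-fold. At a q of 0.01 there were 439 and 336 calls, and with a normal p from the deposited test statistic 95 and 29. Of the 126 tested genes listed at 0 in 1 group, 64 were called. An exact 0 in such a table can be a failed estimate, so genes at 0 are given only as listed at 0.

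Genes of the primitive endoderm, the extraembryonic layer that forms yolk sac and basement membrane, rose together. Of 25 tested members, 18 were called higher, 0 lower and 7 were not called, with 18 higher and 0 lower adjusted over the list alone. The list was enriched among genes called higher (odds ratio 35.5, Fisher's exact test, BH-adjusted p = 1.77e-14), and its median log2 ratio was 2.95 (interquartile range 2.12 to 3.81). Besides Dab2, Col4a1, Col4a2 and Gata4, the list included Sox7 (0.367 to 11.3 FPKM), Pdgfra (1.22 to 14.5 FPKM), Gata6 (1.24 to 12.9 FPKM), Lamb1 (13.9 to 128 FPKM) and Sparc (180 to 788 FPKM) in the authors' deposited table. Sox17 (0.710 and 46.1 FPKM, q = 0.292), Cited1 (0.774 and 37.8 FPKM, q = 0.498) and Foxa2 (0.904 and 9.92 FPKM, q = 0.493) were not called in the authors' deposited table. Of the tested members, 5 lie in segments of chromosomes 8 and 14 where most expressed genes were higher in the knockout. Col4a1, Col4a2 and Gata4 are among them, and all 5 were called higher. Outside those segments, 13 of 20 were called higher (odds ratio 31.6, Fisher's exact test, adjusted p = 1.64e-10).

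Of the other developmental transcription factors, 11 of 40 tested members were called higher, 1 lower and 28 were not called (odds ratio 5.18, Fisher's exact test, adjusted p = 0.0016). Their median log2 ratio was 0.49, and 12 were higher and 2 lower adjusted over the list alone. The largest gains were Pitx1 (0.430 to 12.1 FPKM), a hindlimb regulator, and Foxq1 (1.55 to 25.6 FPKM). Dmrt1, a testis regulator, fell from 49.4 to 16.6 FPKM. Of the 166 members in the table, 126 were not tested. The median control FPKM of the list was 0.22, and 0 tested genes had an FPKM under 1 in both groups. A member under 1 FPKM in control cells was thus tested only if it was higher in knockout cells. This selection can favour higher calls in lists of genes low in control cells, and its part in the odds ratio was not measured. Among 39 Hox genes, 7 were tested and 1 was called: Hoxb8, listed at 0 in control and at 1.59 FPKM in knockout cells.

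**Figure D2:**
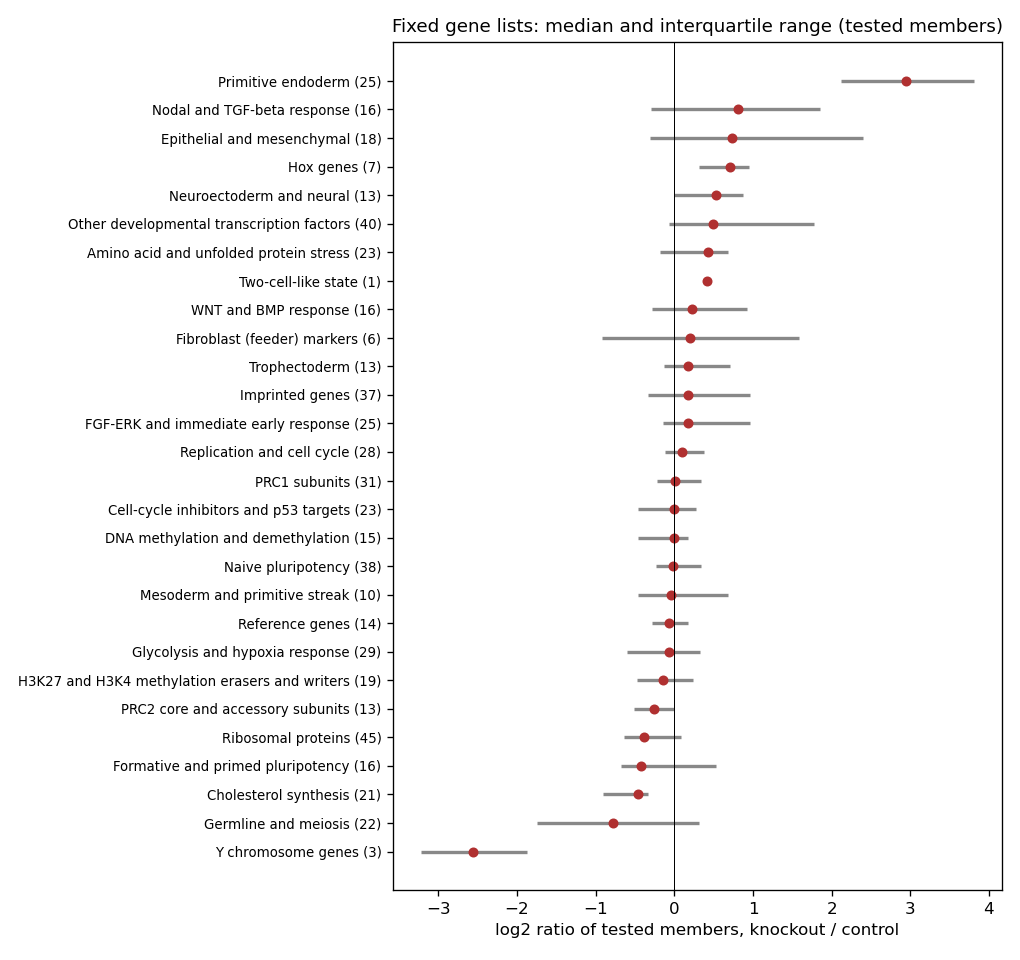
Median (dot) and interquartile range (bar) of log2((knockout FPKM + 0.5)/(control FPKM + 0.5)) over the tested members of each of the 28 gene lists, with the number tested in brackets. The primitive endoderm list has the highest median, 2.95, and the Y chromosome list the lowest, -2.56.

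Imprinted genes, expressed from 1 parental copy, moved both ways. Of 37 tested members, 9 were called higher, 4 lower and 24 were not called, and the list was enriched among genes called higher (odds ratio 4.38, Fisher's exact test, adjusted p = 0.0136). Phlda2 went from 5.59 to 127 FPKM, Grb10 from 2.25 to 32.2 FPKM and the cell-cycle inhibitor gene Cdkn1c from 3.97 to 35.8 FPKM. Plagl1, listed at 0 in knockout cells, and Nnat were lower. The median log2 ratio of the list was 0.17, with an interquartile range of -0.34 to 0.96. Adjusted over the list alone, 9 were higher and 6 lower.

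No list passed the threshold among genes called lower (Fisher's exact test), and 5 had an unadjusted p under 0.05. The germline and meiosis list came nearest: of 22 tested members, 5 were called lower, 0 higher and 17 were not called (odds ratio 4.61, Fisher's exact test, adjusted p = 0.0818). Its median log2 ratio of -0.78 lay at percentile 0 among 10000 random lists matched on expression. The bootstrap interval of that median, -1.56 to 0.02, included 0. Of the members, 8 were lower and 2 higher adjusted over the list alone. Stra8, which starts meiosis, was listed at 0 in knockout cells, and Syce1, a synaptonemal complex gene, fell from 7.57 to 1.49 FPKM. The list passed the threshold in a Mantel-Haenszel test stratified by expression, with an odds ratio of 9.32. It also passed for calls of at least 2-fold (odds ratio 7.80, Fisher's exact test, adjusted p = 0.0331). It missed at a q of 0.01 (Fisher's exact test, adjusted p = 0.146), with 1 member per 200 kb run (Fisher's exact test, adjusted p = 0.0978), and, in alternatives chosen after seeing the data, without the shifted segments (Fisher's exact test, adjusted p = 0.0530). Without genes listed at 0, Stra8 among them, it missed with 4 of 21 called lower (odds ratio 3.81, Fisher's exact test, adjusted p = 0.194), an alternative also chosen after seeing the data.

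Several keratin and other epithelial genes were called higher. In the epithelial and mesenchymal list, 5 of 18 tested genes were called higher, 2 lower and 11 were not called, with an odds ratio of 5.22 for higher calls that missed the threshold (Fisher's exact test, adjusted p = 0.0696). It passed in the Mantel-Haenszel test (odds ratio 5.38). It also passed at a q of 0.01 (odds ratio 9.67, Fisher's exact test, adjusted p = 0.00665) and for calls of at least 2-fold (odds ratio 7.91, Fisher's exact test, adjusted p = 0.0199). It missed with 1 member per 200 kb run, which counts the neighbours Krt8 and Krt18 once (4 of 16, odds ratio 4.52, Fisher's exact test, adjusted p = 0.168). It also missed in alternatives chosen after seeing the data, without the shifted segments (Fisher's exact test, adjusted p = 0.107) and without genes listed at 0 (Fisher's exact test, adjusted p = 0.0601). The list median of 0.73 lay at percentile 100 among random lists, but its bootstrap interval, -0.28 to 2.01, included 0. Krt18 went from 9.55 to 117 FPKM, Krt8 from 6.11 to 52.9 FPKM and Epcam from 11 to 92.7 FPKM. Zeb1, a repressor of epithelial genes, fell from 9.06 to 4.12 FPKM, and Mmp2 from 13 to 5.43 FPKM. The amino acid and unfolded protein stress list had 6 of 23 tested genes called higher and 1 lower (odds ratio 4.79, Fisher's exact test, adjusted p = 0.0542). It passed in the Mantel-Haenszel test (odds ratio 4.92), and, in alternatives chosen after seeing the data, without the shifted segments (odds ratio 5.93, Fisher's exact test, adjusted p = 0.0199) and without genes listed at 0 (odds ratio 4.97, Fisher's exact test, adjusted p = 0.0456). It missed at a q of 0.01 (Fisher's exact test, adjusted p = 0.0869) and for calls of at least 2-fold (Fisher's exact test, adjusted p = 0.144). The list median of 0.42 lay at percentile 99.98, but its bootstrap interval, -0.17 to 0.59, also included 0. Its calls included Chac1 (31.7 to 156 FPKM), Atf4 (114 to 294 FPKM) and Herpud1 (17.7 to 61.5 FPKM), while the chaperone gene Hspa5 fell from 180 to 114 FPKM.

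Most naive pluripotency genes were not called, as was true of all tested genes, of which 12.9% were called. In the naive pluripotency list, 5 of 38 tested genes were called higher, 2 lower and 31 were not called, and the median log2 ratio was -0.01. Pou5f1 (1312 and 1212 FPKM), Nanog (105 and 90.0 FPKM), Sox2 (602 and 486 FPKM) and Esrrb (795 and 730 FPKM) were not called. Tdh (73.1 to 253 FPKM) and Spp1 (82.8 to 259 FPKM) rose, and Utf1 (352 to 215 FPKM) and Tcea3 (121 to 54.1 FPKM) fell. 3 list members lie in the shifted segments, Tdh among them. In the formative and primed list, 3 of 16 tested genes were called higher and 4 lower. Krt19 and Cldn6 (4.71 to 74.9 FPKM) were higher, and Sox4 (37.6 to 11.5 FPKM) and the retinoid-binding gene Crabp1 (106 to 30.4 FPKM) lower. Among 15 tested DNA methylation genes, 3 were called lower and 0 higher. Dnmt3a, a de novo DNA methyltransferase, fell from 100 to 22.7 FPKM and Mbd3 from 207 to 124 FPKM.

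No growth or signalling list passed the threshold. In the FGF-ERK list, Atf3 (1.98 to 48.4 FPKM) and Jun (1.86 to 13.5 FPKM) rose, and Etv4 (161 to 88.3 FPKM) and Etv5 (130 to 80.1 FPKM) fell, among 4 higher and 3 lower calls of 25 tested. In the Nodal and TGF-beta list, 3 of 16 tested genes were called higher, with Ctgf (9.21 to 53.9 FPKM) and Cyr61 (16.1 to 61.8 FPKM) first, and Inhbb fell from 41.1 to 13.5 FPKM. Its median log2 ratio of 0.82 lay at percentile 100 among random lists, of which the central 95% reached 0.39. The 95% bootstrap interval of that median, -0.22 to 1.83, included 0. The WNT and BMP list had 3 higher and 1 lower of 16 tested, with Gata2 (0.547 to 4.74 FPKM) and Id2 (4.56 to 16.9 FPKM) higher and Cdx1 (21.3 to 7.08 FPKM) lower. Cdkn1b rose from 47.2 to 119 FPKM and Phlda3 fell from 58.8 to 34.7 FPKM in the cell-cycle inhibitor and p53 list, which had 3 higher and 1 lower call of 23 tested. Of 28 replication genes, 2 were higher, Tyms (11.1 to 19.7 FPKM) and Mki67 (15.6 to 24.2 FPKM), and 1 lower, Aurkb (36.1 to 21.2 FPKM).

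Cholesterol synthesis and ribosomal protein genes had medians below those of most random lists. In the cholesterol synthesis list, 4 of 21 tested genes were called lower and 0 higher, led by Msmo1 (14.4 to 4.72 FPKM), and the list median of -0.46 lay at percentile 0.06 among random lists. Msmo1 lies in a segment of chromosome 8 where expression was lower in the knockout. Of 45 tested ribosomal protein genes, 6 were called lower and 0 higher, such as Rpl15 (96.6 to 37.2 FPKM) and Rps19 (399 to 219 FPKM), with a list median of -0.38 at percentile 0.465. Many ribosomal protein genes have near-identical pseudogenes, so their FPKM values are uncertain. The glycolysis and hypoxia list split evenly, with 5 of 29 tested genes higher, such as P4ha2 (4.03 to 20.6 FPKM) and P4ha1 (15.2 to 46.6 FPKM), and 5 lower, such as Eno1 (83.3 to 35.3 FPKM) and Pgam1 (20.4 to 10.3 FPKM).

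In the remaining lists the counts were small. Among 19 tested H3K27 and H3K4 enzymes, Ash2l (100.5 to 213 FPKM), inside a raised segment of chromosome 8, and Kmt2c (5.04 to 8.30 FPKM) were higher, and Kdm1a (76.8 to 49.4 FPKM) and Kmt2d (22.9 to 15.2 FPKM) lower. Of 31 tested PRC1 genes, 1 was called, Bcorl1 (4.45 to 2.08 FPKM). Among 13 tested trophectoderm genes, Krt18 and Krt8 were higher and Tfap2c (16.9 to 7.41 FPKM) lower. The mesoderm list had 1 higher and 1 lower call of 10 tested, Gata2 and Cdx1, and the neural list 1 higher of 13 tested, Nkx6-2 (12.1 to 77.8 FPKM). The fibroblast list had Thbs1 (0.178 to 1.78 FPKM) higher and Fbln1 (38.9 to 18.5 FPKM) lower of 6 tested. Among 14 tested reference genes, 1 was called, Gusb (3.23 to 9.58 FPKM). In the two-cell list 1 gene was tested and 0 were called.

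The third comparison asked whether differences clustered along chromosomes, since a knockout line can differ from its control in karyotype. They did, most of all on chromosome 14 and in parts of chromosome 8. The median log2 ratio of 405 expressed genes on chromosome 14 was 0.71, against -0.06 to 0.09 for the central 95% of random gene sets of that size, and 116 genes there were called higher against 10 lower. The median of chromosome 8 as a whole, 0.0075, lay inside its random range of -0.05 to 0.07. Smaller shifts lay outside the central 95% on chromosomes 1 (0.11), 3 (0.10) and 13 (0.09), and on chromosomes 4 (-0.05), 5 (-0.09), 7 (-0.09) and 17 (-0.05). That of chromosome 7 lay below all of its random sets, those of 4 and 17 passed their bounds only just, and that of 13 moved inside its range in both alternatives run. Running medians over 50 neighbouring genes, a method chosen after seeing the data, marked 3 segments. On chromosome 14, the 289 expressed genes from 40.9 to 123 Mb had a median log2 ratio of 0.92 (95% bootstrap interval 0.85 to 1.04), and 114 were called higher and 1 lower. On chromosome 8, the 129 expressed genes from 3.39 to 33.9 Mb had a median of 0.92 (0.82 to 1.01), with 50 called higher and 1 lower. The 110 genes from 34.1 to 70.6 Mb had a median of -0.56 (-0.74 to -0.38), with 5 called higher and 29 lower. Segment ends and medians depended on the window and its threshold: with 25 genes, segments were marked up to 73.3 Mb on chromosome 14, and the lowered segment of chromosome 8 held 40 genes with a median of -0.96. These segments held 4.44% of tested genes and 13.6% of calls. Outside them, 615 genes were called higher and 654 lower, and the medians of the autosomes and of X lay between -0.09 and 0.11. The mitochondrial genome had a median of 0.44 over 8 genes and Y one of -2.56 over 3.

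**Figure D3:**
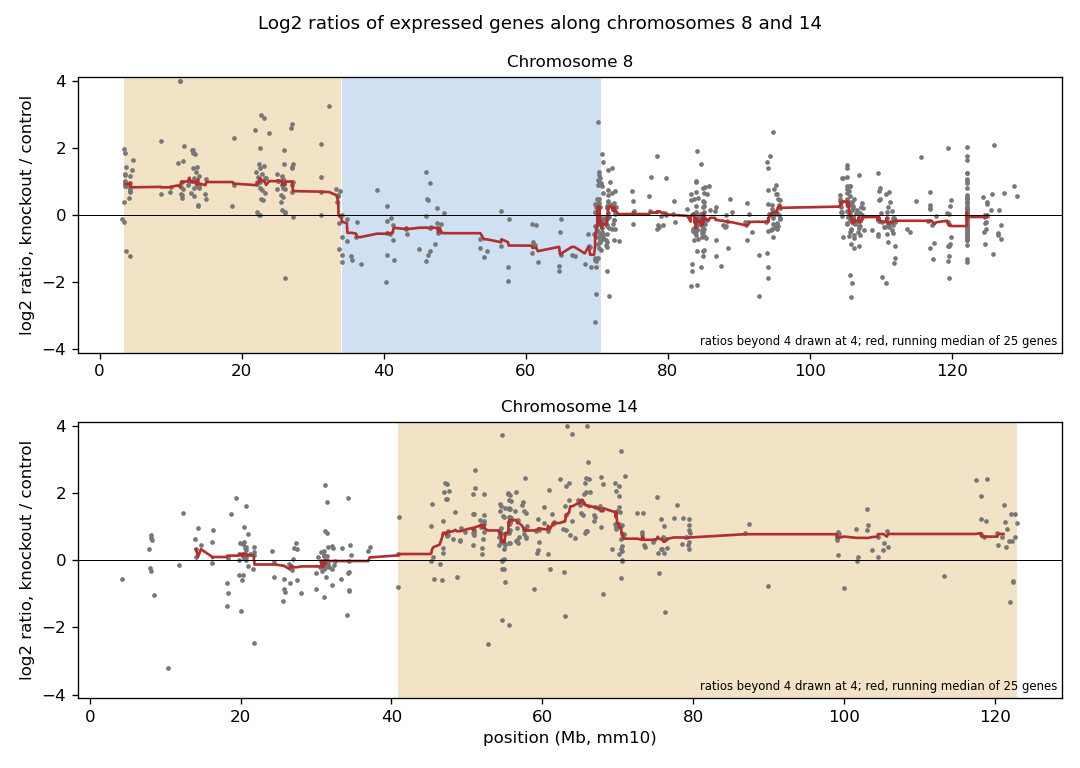
Log2((knockout FPKM + 0.5)/(control FPKM + 0.5)) of genes with FPKM of 1 or more in either group (grey points) against position in Mb on chromosomes 8 and 14, with a running median of 25 genes (red line), points beyond 4 drawn at 4, and the 3 shifted segments shaded (tan higher, blue lower in the knockout). The segment medians are 0.92 and -0.56 on chromosome 8 and 0.92 on chromosome 14.

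Neighbouring genes were called in the same direction more often than chance would give. There were 200 such neighbouring pairs, against a mean of 95.2 in shuffles of the calls and at most 129 in any of 10000 shuffles. Outside the 3 segments there were 113 pairs against a mean of 73.9 in shuffles. On the Y chromosome, 3 genes were tested and all 3 had lower values in knockout cells in the authors' deposited table. Ddx3y (2.44 FPKM in control) was listed at 0 and called, while Eif2s3y (10.7 and 0.258 FPKM, q = 0.447) was not called in the authors' deposited table.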

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

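Alternatives that left out genes listed at 0 or the shifted segments, gene span matching, other window sizes and the calls of Mtf2 at other thresholds were chosen after seeing the data. A q of 0.01 gave 439 higher and 336 lower calls, a 2-fold minimum 318 lower calls, and a normal p from the test statistic 95 higher and 29 lower; the first 2 are stricter by construction, and the cause of the third was not tested. At a q of 0.01 the call of Mtf2 (log2 ratio -0.73, q = 0.0496) ended, as it did with the normal p (log2 ratio -0.73, q = 0.755). Of lists enriched among higher calls, the expression-stratified test gave 5 in place of 3, adding the epithelial and the stress list. A q of 0.01 and the 2-fold minimum each added the epithelial list, and leaving out the shifted segments or the genes listed at 0 each added the stress list, giving 4. Of lists enriched among lower calls there were 0, and 1 each in the stratified test (germline), at a q of 0.01 (cholesterol), at 2-fold (germline) and without the shifted segments (formative pluripotency); the cause of these changes was not tested. The FPKM filter removed no tested gene and recomputed BH repeated the deposited q, so these say nothing about stability. The primitive endoderm, developmental transcription factor and imprinted lists stayed past the threshold in the 6 other alternatives run, with odds ratios of 31.6 to 45.9, 4.88 to 7.88 and 4.16 to 6.97. The shift of chromosome 14 was 0.69 to 0.76, and 36 of 41 values of other chromosomes kept their side of the random range. Chromosome 13 moved inside it at an FPKM of 5 (0.01) and with the trimmed mean (0.10), while 11 (-0.09) and X (0.13) moved outside at an FPKM of 5 and 19 (-0.03) with the trimmed mean. Pseudocounts cannot change the sign of a gene's ratio and centring moves all genes alike, so no stability of single genes was tested. Of 112 list medians under other pseudocounts, span matching or without the shifted segments, 108 stayed on the same side of the random range. The 4 others, of the developmental and formative lists, moved inside it. Windows of 25 genes, with a threshold of 0.79 in place of 0.51, gave 4 segments: on chromosome 14 they marked 40.9 to 54.6 and 55.1 to 73.3 Mb, and the lowered segment of chromosome 8 shrank from 110 genes (median -0.56) to 40 (-0.96). Windows of 75 genes gave 3, with 138 genes lowered (-0.51) and 31.2 to 123 Mb marked on chromosome 14. No paired analysis was possible because the table has no values per replicate; leave-one-out and count-based tests were not run for the same reason. Depth per library is unknown, so no limit from it can be given.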

Other observations

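All tests in this part, with their bounds, and both gene lists of its first paragraphs were chosen after the data had been seen. Lysosomal enzyme and membrane protein genes were higher in knockout cells: of 42 tested, 21 were called higher and 1 lower, with a median log2 ratio of 1.02. Leaving out the genes noticed beforehand, 14 of 35 were called higher (odds ratio 9.22, Fisher's exact test, BH-adjusted p = 1.05e-07), with a median log2 ratio of 0.87. In the authors' deposited table, the lysosomal membrane gene Lamp1 went from 75 to 291 FPKM, the cathepsin genes Ctsl from 79.8 to 280 FPKM and Ctsz from 93.2 to 221 FPKM, the hexosaminidase gene Hexa from 73.3 to 199 FPKM and the legumain gene Lgmn from 44.8 to 166 FPKM. Asah1, on the lowered segment of chromosome 8, fell from 34.8 to 20.4 FPKM, and Lamp1 lies in the raised segment of the same chromosome.

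Target genes of the YAP and TEAD regulators were tested because genes such as Ctgf, Cyr61, Ankrd1 and Amot (0.402 to 18.3 FPKM) stood out. Of 26 tested members, 8 were called higher and 1 lower. With the genes noticed beforehand left out, 2 of 20 tested members were called higher (odds ratio 1.51, Fisher's exact test, adjusted p = 0.962), which missed the threshold. Apolipoprotein E, Apoe, was among the most abundant genes called higher, at 1458 FPKM in control and 4298 FPKM in knockout cells.

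The first pattern weighed is the shift of log2 ratios along parts of chromosomes 8 and 14. Because the segments were found from the ratios themselves, they were found again from every second expressed gene and measured on the genes held out. With a threshold of 0.71 in place of 0.51, this marked narrower segments, at 3.15 to 32.9 and 48.1 to 70.0 Mb on chromosome 8 and 46.4 to 75.2 Mb on chromosome 14. In the lowered segment, the one nearest to 0, 20 held-out genes had a median of -0.69 (95% bootstrap interval -1.03 to -0.31). The shift was thus not limited to a few strongly changed genes. Segments marked by running medians could hardly show otherwise, so this outcome is no independent test. Release of genes silent in control cells does not account for the whole rise of the raised segments. The median was 0.83 (0.65 to 1.14) over 30 held-out genes already at 10 FPKM or more in control cells. This was the raised segment with the smaller value. Of held-out genes with a mean FPKM of 10 or more, at least 91.7% in each segment lay on its side of 0. That lowest share was of 12 genes in the narrower lowered segment. Over the lowered segment of 34.1 to 70.6 Mb, found without holding genes out, 79.4% of 63 such genes were lower. A different copy number of these segments in control and knockout cells may give such shares, but it cannot be told apart from a regional effect of losing MTF2. The pooled values do not separate knockout lines and no genomic DNA reads were analysed, so the shares could not decide between the explanations.

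The second pattern is the rise of primitive endoderm genes. The location of members inside the shifted segments does not account for the whole rise. The 20 tested members outside the segments had a median log2 ratio of 2.78 (2.11 to 3.14). An effect of genes inside the segments, such as Gata4, on members outside them was not tested. RNA from feeder fibroblasts is argued against: Col1a1, Col1a2 and Col3a1, abundant in fibroblasts, reached at most 0.773 FPKM in knockout cells, and the labels name gelatin-coated plates. A subset of knockout cells that turned into endoderm may account for it, but this cannot be told apart from a smaller rise in every cell. The naive pluripotency list, which such a subset would dilute, had a median of -0.011 (-0.15 to 0.32), and a small subset would not move it. No values per cell or per library were used, and a difference between clones, unrelated to MTF2, is not excluded.

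The third pattern is large differences without a call. Of 110 tested genes with a log2 ratio beyond 3 in either direction, an 8-fold difference, 56 were not called, among them Cyp26a1, a retinoic acid hydroxylase (0.329 and 166 FPKM, q = 0.476), Clic6 (0.192 and 55.3 FPKM, q = 0.333) and Sox17. Of the uncalled genes, 29 reached 10 FPKM in their higher group and 27 did not, against 42 and 12 of the called ones. An uncalled gene had the smaller higher-group FPKM than a called one with a chance of 0.69 (0.58 to 0.79). Too few reads in both groups thus stay open as a part of it, since FPKM is not a read count and depth is unknown. A value near 0 in the lower group may contribute: among genes at 10 FPKM or more in the higher group, an uncalled gene had the smaller lower value than a called one with a chance of 0.78 (0.67 to 0.88). The genes were not compared at equal higher-group FPKM, so a value near 0 in the lower group is not separated from low expression in both. Spread between the libraries of a group cannot be told apart from a value near 0 either. Of the called genes, 14 also had a lower value under 1 FPKM, and no values per library were at hand.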
